A study of Mus musculus with 9 samples.

How the data were processed

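The series holds 9 RNA-seq libraries of mouse Treg cells pooled from spleen and lymph node, 3 in each of 3 groups named by the labels: YFP-positive Thpok- and LRF-deficient cells, YFP-negative CD25-high animal controls from the same mice, and YFP-positive genetic controls from other mice. RNA was extracted with a column kit, and libraries were made with a low-input template-switching kit and a transposase kit, per the labels. Reads were converted with bcl2fastq 1.8.4 and aligned with STAR 2.4.0h to mm10, per the submitters' processing notes, which also name limma without a version or a role. The counting tool, the annotation, any filter on genes and the normalization settings are not given in the sources used here.

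The deposited table holds log2 values that the authors had already normalized. The linear values of each library sum to between 999258 and 999307, and the lowest (-7.77) and highest (13.42) values are the same in all 9 columns, so the unit was read from the values as log2 CPM, quantile-normalized across libraries. Between 8.00% and 11.4% of genes lay at the lowest value in a library, which probably marks genes without a read. Total counts cannot be recovered, so the depth is unknown and no counting interval is given. The table has 13702 rows, of which 4 were exact duplicates and were dropped, leaving 13698 genes; 7550 of them have a mean log2 value at or above that of 10 CPM. Symbols were matched to GENCODE M21 (GRCm38) for coordinates, which held 12876 of them (94.0%), and to symbol synonyms for the gene lists.

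All values were used as deposited, with no pseudocount and no filter. The tests, the rule for named genes, the 26 gene lists and the alternatives were set before the data were examined, except where stated. The plan was a count-based test for counts and limma-trend for log2 values. Since the table holds log2 values, limma-trend was used (limma 3.58.1 in R 4.3.3; data.table, version 1.17.8, for reading), with a single model of the group means over all 9 libraries, 3 two-sided contrasts, and Benjamini-Hochberg adjustment over all genes at an FDR under 0.05. The 3 comparisons were deficient cells against genetic controls, deficient cells against animal controls, and genetic against animal controls; genes called with the same sign against both controls were intersected. The chance overlap was simulated in 50 draws of unchanged groups that share the deficient libraries. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.1, so no such test is reported.

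The rule for named genes was: Zbtb7b, Zbtb7a, Foxp3, Il2ra, Cd4, Cd8a, Cd8b1 and Runx3 always; per comparison the 8 genes with the largest rise and the 8 with the largest fall (5 and 5 between the controls) among called genes with a mean of at least 10 CPM in the higher group and no overlap between groups, without predicted genes, Rik clones and receptor segments; up to 4 members of each list by adjusted p; and the 8 and 8 with the largest smaller fold against both controls. Other genes in the text are called members of the lists, and those in the closing part were chosen after their values were seen, as stated there. Genes with a group mean under 1 CPM are given as levels, except that the closing part also gives folds of Xkr6 and Zbtb7b, which depend on the lowest values.

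The 26 gene lists were: Treg signature, IL-2 and STAT5 responsive genes, CD8 lineage and cytotoxic genes, CD4 lineage genes, helper effector cytokines and regulators, effector Treg genes, central or resting Treg genes, chemokine receptors, integrins and homing, cell cycle, apoptosis, interferon response, T cell receptor-induced genes, co-inhibitory receptors, glycolysis, cholesterol synthesis, oxidative phosphorylation and the TGF-beta pathway, and markers of B cells, plasma cells, myeloid cells, NK cells, gamma-delta T cells, erythroid cells and platelets, stromal cells, naive T cells and follicular helper T cells. They were tested with camera from limma at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list moves on balance in a single direction. Of the lists, 25 had measured members. Several lists share members: Tigit, for example, is in the Treg signature, effector Treg and co-inhibitory lists, and Pdcd1 is in the effector Treg, co-inhibitory and follicular helper lists.

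The deficient cells and animal controls bear the same mouse numbers. After group means were removed, the libraries of the same mouse had correlations across 7550 genes of 0.0483, 0.0202 and 0.0170, against between -0.0304 and 0.00803 for libraries of different mice; genes are not independent replicates, and no test was made of these. The plan set a fit without a mouse term as the main one, and the mouse was tried as a fixed and as a random term (consensus correlation 0.0493). No sequencing batch or date is given in the sources used here. Correlations across genes ranged from 0.790 to 0.862 between libraries of a group and from 0.742 to 0.859 between groups. The first principal component, with 21.8% of the variance, separated the deficient libraries (32.9 to 43.1) from all others (at most -7.68), and animal control 232614 stood apart on the second (58.1, 15.9% of the variance). On the third, with 12.8%, genetic control 8619 lay lowest (-42.5, the other genetic controls at 9.70 and 11.5), followed by deficient library 432614 (-29.3).

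The tests were checked on simulated data with the real means and residual spread and 200 genes changed by known amounts in each of 10 draws. The changed genes were drawn from those with a mean of at least 10 CPM. Values were drawn independently for each gene, with no lowest value imposed. Against the genetic controls 15.7% of changes of 1 log2 unit, 49.9% of 2 units and 89.7% of 4 units were recovered, with 5.29% false calls; against the animal controls 15.1%, 54.0% and 89.8% were recovered, with 4.46% false calls. A list shifted by 1 unit was called in 10 of 10 draws in both comparisons, and of 170 tests of unshifted lists 3 were called against the genetic controls and 1 against the animal controls. As the simulated genes were independent, these counts do not cover lists with correlated members. In the real data the estimated correlation reached 0.704, for erythroid and platelet markers. Alternatives tried were each library left out in turn, the 6 compared libraries alone, limma without a trend, quantile normalization repeated, the genes with the lowest means left out (10273 kept), an FDR under 0.01, a minimum log2 change of 1, and the mouse terms. Alternatives chosen after seeing the data were values under 1 CPM raised to 1 CPM, robust moderation, trimmed-mean rescaling, genes with a mean of at least 10 CPM alone, genetic control 8619 and animal control 232614 both left out, and Zbtb7b and Zbtb7a left out of the gene lists. Pseudogene sequences were compared with GENCODE M21 transcripts using blastn 2.17.0. Reads, exons, variants and isoforms were not analysed here, because the table holds values per gene.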

Results

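RNA from sorted mouse regulatory T (Treg) cells of spleen and lymph node was sequenced in 9 libraries, 3 in each of 3 groups. The deficient cells were Treg cells sorted as YFP-positive that lacked Thpok and LRF, the transcription factors encoded by Zbtb7b and Zbtb7a; they came from female mice in which YFP and Cre are made from a Foxp3 allele. The animal controls were YFP-negative, CD25-high cells from those same 3 mice, which used the unmodified Foxp3 allele and kept both factors. The genetic controls were YFP-positive cells from 3 other female mice that carried the Foxp3-YFP-Cre allele and kept both factors. All 3 groups were sorted as negative for MHC class II, per the labels. Values are quantile-normalized log2 CPM (read counts scaled to a common total) as deposited, for 13698 genes. The read depth of the libraries is unknown, because the normalized values of each library sum to nearly the same total. Levels are given below as mean CPM ± SD with n = 3 libraries per group, and changes as log2 fold change ± SE with n = 3 against 3 and a Benjamini-Hochberg adjusted p from limma. Coordinates are 1-based on GRCm38.

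The deleted genes were read first. Zbtb7b (chromosome 3, 89377644 to 89394776), which directs T cells to the CD4 lineage, measured 0.260 ± 0.110 CPM in the deficient cells, 115 ± 30.3 CPM in the genetic controls and 93.7 ± 15 CPM in the animal controls. It fell against both controls (adjusted p = 1.03e-04 and 8.75e-05), and every deficient library lay below every control library. Zbtb7a (chromosome 10, 81135220 to 81152995) measured 89.5 ± 12.6 CPM in the deficient cells, 90.3 ± 21 CPM in the genetic controls and 112 ± 19.3 CPM in the animal controls. Its log2 differences of 0.01 ± 0.25 (adjusted p = 1) and -0.31 ± 0.25 (adjusted p = 0.704) were within the spread between libraries. Which exons of Zbtb7a were deleted is not given in the sources used here, and the deposited values are per gene, so the Zbtb7a value does not test its deletion.

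**Figure D1:**
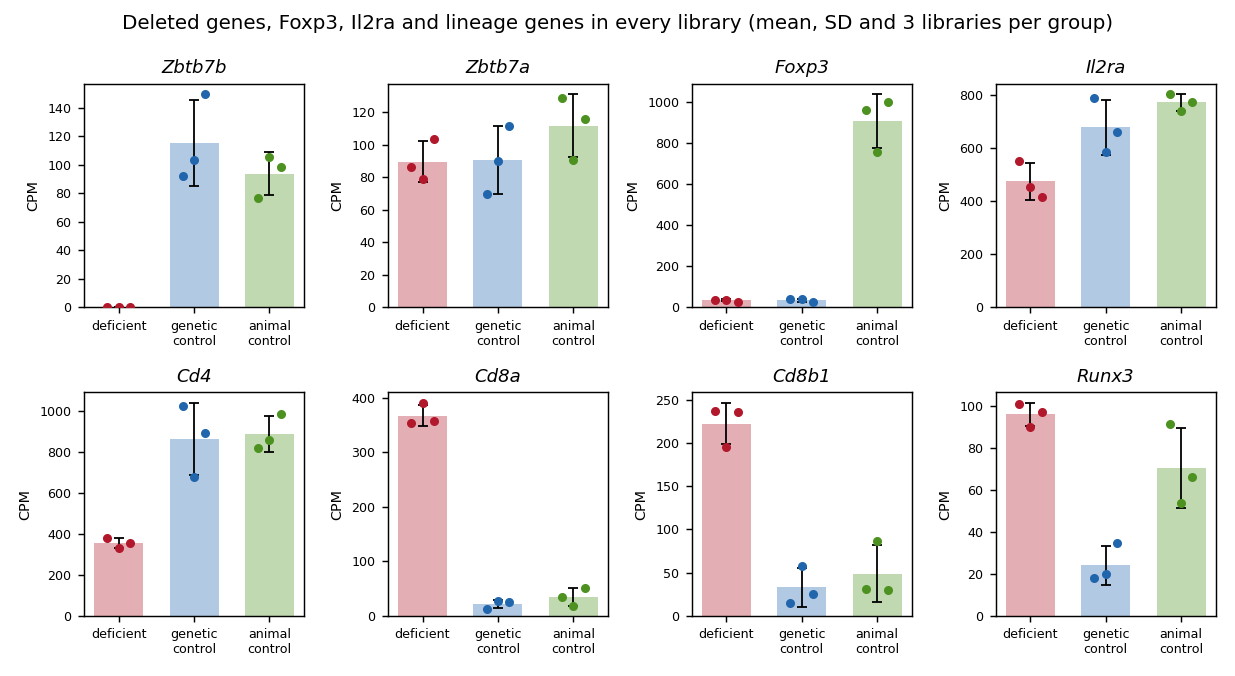
Level in CPM (linear axis from 0) of the deleted genes, Foxp3, Il2ra and the lineage genes Cd4, Cd8a, Cd8b1 and Runx3 in the deficient cells, genetic controls and animal controls. Bars are means, error bars are SD, and points are the 3 libraries of each group; Cd8a averaged 367 CPM in the deficient cells against 21.9 and 34.5 CPM in the controls.

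The comparison of deficient cells with genetic controls asks what the loss of both factors goes with among cells that share the Foxp3-YFP-Cre allele and the YFP gate, though not the mice. Cd8a (chromosome 6, 71373427 to 71379173), which encodes the CD8 co-receptor of MHC class I-restricted T cells, rose from 21.9 ± 7.56 to 367 ± 19.9 CPM (log2 fold change 4.14 ± 0.40, adjusted p = 0.00188). Cd4 (chromosome 6, 124864692 to 124888221), the co-receptor of helper and most regulatory T cells, fell from 866 ± 175 to 355 ± 25.7 CPM (-1.27 ± 0.15, adjusted p = 0.00488). Ccr9, a chemokine receptor that guides lymphocytes to the small intestine, rose from 23.6 ± 17.8 to 415 ± 73.1 CPM (4.43 ± 0.59, adjusted p = 0.00977). Itgb1, the integrin beta-1 chain, fell from 501 ± 58.9 to 84.3 ± 5.64 CPM (-2.57 ± 0.17, adjusted p = 1.48e-04). Foxp3 (chromosome X, 7573644 to 7595245), the transcription factor that defines Treg cells, measured 32.2 ± 5.02 CPM in the deficient cells and 33.3 ± 7.38 CPM in these controls (-0.03 ± 0.25, adjusted p = 0.992). Il2ra, which encodes CD25, measured 473 ± 70.2 and 676 ± 104 CPM and did not pass the test (-0.52 ± 0.14, adjusted p = 0.160).

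Genes of the Treg programme were lower in the deficient cells than in the genetic controls. In the Treg signature list, 1 of 39 measured members rose and 9 fell, or 3 and 14 adjusted over the list alone (list adjusted p = 3.84e-09, and adjusted p = 0.0147 with an estimated correlation). The members that fell included Nrp1, a co-receptor for semaphorins found on thymus-derived Treg cells (log2 fold change -2.42 ± 0.27, adjusted p = 0.00428), Nt5e, which encodes the ectoenzyme CD73 (-1.56 ± 0.17, adjusted p = 0.00323), and Capg, an actin-capping protein (-1.73 ± 0.16, adjusted p = 0.00111). Ecm1, a secreted matrix protein, was the member that rose (0.86 ± 0.14, adjusted p = 0.0240). Among effector Treg genes, 0 of 36 measured members rose and 7 fell, or 2 and 24 adjusted over the list alone (list adjusted p = 2.26e-19, and adjusted p = 0.0147 with an estimated correlation). Lgals1, which encodes the lectin galectin-1, was one of those (-2.10 ± 0.25, adjusted p = 0.00473). Il1rl1, which encodes the receptor for IL-33, averaged 0.0302 ± 0.0287 CPM in the deficient cells against 10.1 ± 0.834 CPM, and Klrg1, an inhibitory receptor of differentiated cells, 0.0331 ± 0.0254 against 21 ± 20.9 CPM. Among IL-2 and STAT5 responsive genes, 1 of 51 measured members rose and 4 fell, or 3 and 7 adjusted over the list alone (list adjusted p = 0.00893, adjusted p = 0.178 with an estimated correlation). Among central or resting Treg genes, 0 of 25 measured members rose and 1 fell, or 0 and 4 adjusted over the list alone, and that list was not called (adjusted p = 0.173).

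Among CD8 lineage and cytotoxic genes, 5 of 22 measured members rose and 0 fell, or 8 and 2 adjusted over the list alone. The list was called upward (adjusted p = 0.00406, and adjusted p = 0.200 with an estimated correlation). Beside Cd8a, the members that rose were Cd8b1, the partner chain of CD8 (2.98 ± 0.53, adjusted p = 0.0370), Runx3, a transcription factor of the CD8 lineage (2.05 ± 0.33, adjusted p = 0.0240), Nkg7, a protein of cytotoxic granules (1.87 ± 0.30, adjusted p = 0.0237), and Xcl1, a chemokine, at 3.41 ± 2.55 against 0.00457 ± 0 CPM. Among CD4 lineage genes, 0 of 15 measured members rose and 2 fell, or 0 and 4 adjusted over the list alone, and the list was called downward (adjusted p = 0.00565, and adjusted p = 0.0647 with an estimated correlation). The members that fell were Cd4 and the deleted Zbtb7b itself, while the list's median log2 fold change was 0.005 and its mean -0.81. Without the deleted genes, Zbtb7b and Zbtb7a, the list was not called by camera (adjusted p = 0.0665, mean -0.26), though fry called it downward (adjusted p = 0.00644).

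The list of chemokine receptor, integrin and homing genes was called downward against the genetic controls, as were the other lists of this paragraph. In the homing list 1 of 29 measured members rose and 4 fell, or 2 and 12 adjusted over the list alone (list adjusted p = 1.58e-11, and adjusted p = 0.0230 with an estimated correlation), with a median log2 fold change of -1.41. Ccr9 was the member that rose. Those that fell were Itgb1, Itgb7, the integrin chain of gut-homing lymphocytes (-0.78 ± 0.11, adjusted p = 0.0107), Gpr183, the receptor for oxysterols that positions cells in lymphoid tissue (-2.84 ± 0.31, adjusted p = 0.00323), and Cxcr6, a chemokine receptor, at 0.105 ± 0.0818 against 43.7 ± 30.4 CPM. In the interferon response list 0 of 40 measured members rose and 2 fell, or 0 and 6 adjusted over the list alone (list adjusted p = 4.51e-05, and adjusted p = 0.159 with an estimated correlation). The members that fell were the surface antigens Ly6a, also called Sca-1 (-5.0 ± 0.24, adjusted p = 3.13e-05), and Ly6c1 (-3.43 ± 0.34, adjusted p = 0.00198). For T cell receptor-induced genes, 0 of 29 measured members rose and 1 fell, or 0 and 1 adjusted over the list alone (list adjusted p = 0.0110, and adjusted p = 0.0647 with an estimated correlation), with Cd83, a membrane protein of activated cells, as the called member (-1.82 ± 0.26, adjusted p = 0.0140). In the helper effector list 0 of 18 measured members rose and 0 fell, or 0 and 5 adjusted over the list alone (list adjusted p = 6.28e-04, and adjusted p = 0.0397 with an estimated correlation), and Rora, a nuclear receptor, had the lowest adjusted p (-1.55 ± 0.35, adjusted p = 0.0904). In the follicular helper T cell list 0 of 12 measured members rose and 1 fell, or 0 and 2 adjusted over the list alone (list adjusted p = 1.06e-04, and adjusted p = 0.0405 with an estimated correlation), with Pdcd1, which encodes the inhibitory receptor PD-1, as the called member (-1.69 ± 0.27, adjusted p = 0.0229).

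Oxidative phosphorylation genes formed the other list called upward, with 0 higher and 0 lower of 40, or 0 and 0 adjusted over the list alone (adjusted p = 0.0492). That call was lost in another form of the test (adjusted p = 0.391 with an estimated correlation) and with fry (adjusted p = 0.220), and with the deleted genes left out of all lists (0.0541). The median log2 fold change of the list was 0.09. Its call was also lost in 6 of the 9 fits without 1 library: without genetic controls 124 and 8619 (adjusted p = 0.234 and 0.0654), without deficient library 432614 (0.315), and without animal controls 142114, 232614 and 432614 (0.0535, 0.0595 and 0.0686). Without genetic control 124 the calls of CD8 lineage (adjusted p = 0.0608), IL-2 responsive (0.0859) and T cell receptor-induced genes (0.0751) were lost too. The last of these was lost without deficient library 142114 as well (adjusted p = 0.0778). Of the 11 lists called against the genetic controls fry called 10, all but oxidative phosphorylation.

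Lists that camera did not call against the genetic controls still held some called genes. Co-inhibitory receptors had 0 higher and 2 lower of 15, or 1 and 2 adjusted over the list alone (adjusted p = 0.0782). That list was called downward by fry (adjusted p = 0.00866) and by camera without deficient library 142114 (adjusted p = 0.0398), and its adjusted p ran up to 0.616 over all settings. Naive T cell markers had 0 higher and 3 lower of 17, or 2 and 4 adjusted over the list alone (adjusted p = 0.659), with a median of 0.08 while the mean and the test pointed down. Glycolysis genes had 0 higher and 1 lower of 30, or 0 and 1 adjusted over the list alone (adjusted p = 0.900). The member that fell was Eno1, an enzyme of glycolysis (-0.58 ± 0.08, adjusted p = 0.0111), while the median of that list (0.06) and its mean (0.05) were positive and the test pointed down. Cholesterol synthesis had 0 higher and 0 lower of 25, or 0 and 1 adjusted over the list alone (adjusted p = 0.402), and the TGF-beta pathway had 0 higher and 0 lower of 19, or 1 and 1 adjusted over the list alone (adjusted p = 0.751). B cell markers had 0 higher and 0 lower of 14, or 1 and 0 adjusted over the list alone (adjusted p = 0.818), with a median of -0.08 while the mean and the test pointed up. Cell cycle and apoptosis genes had 0 members higher and 0 lower of 37 and 28 measured, and 0 and 0 adjusted over the list alone (adjusted p = 0.270 and 0.981). The apoptosis list had a median of -0.009 beside a mean of 0.007. Markers of plasma cells, myeloid and dendritic cells, NK cells, gamma-delta T cells and erythroid cells and platelets had 0 members higher and 0 lower of 5, 14, 9, 5 and 8 measured, and 0 and 0 adjusted over the list alone (adjusted p = 0.402, 0.827, 0.880, 0.109 and 0.900). None of the 14 stromal and endothelial markers was measured.

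Of 13698 genes tested, 119 changed against the genetic controls (limma, FDR under 0.05), 46 higher and 73 lower, and 1455 had an unadjusted p under 0.05. The groups did not overlap for 15.7% of genes, where chance gives 10%. By fold change, the genes named by rule as highest were Cpxm1, Zfp385a, Mcam, Ccdc102a, Tubb3, Xkr6, Notch3 and Bai2, each under 1 CPM in the genetic controls and between 11.5 and 44.3 CPM in the deficient cells. Of these, Xkr6 was about as high in the animal controls, which kept both factors. Its difference thus goes with the mice and not with the loss of both factors. The lowest were Ttn, Ptpn5, Arc, Acot11, Klhl5, Map6, Csf1 and Lgmn, each under 0.1 CPM in the deficient cells and between 10.9 and 29.5 CPM in the genetic controls. For such genes the fold depends on the lowest values in the file, and levels are given in place of folds. The count fell to 71, 48 and 49 without genetic controls 124, 8619 and 8800. It was 64, 72 and 68 without deficient libraries 142114, 232614 and 432614, and 87, 93 and 72 without the animal controls of those numbers. On the 6 libraries compared alone it was 22. Without the trend limma called 85, 46 higher and 39 lower, of which 64 were among the 119, so the excess of lower genes depends on the fit. The count was 21, 12 higher and 9 lower, without both genetic control 8619, which had the most myeloid (746 summed CPM) and erythroid (113 summed CPM) transcripts, and animal control 232614. Of 67 called genes followed through all fits, 30 passed in every fit without 1 library. Zbtb7b, Cd8a, Cd4, Ccr9, Itgb1, Nrp1, Nt5e, Capg, Lgals1, Gpr183, Cxcr6, Ly6a, Ly6c1, Arc, Ttn and Ptpn5 were among these. The others missed the threshold in at least 1 such fit, with adjusted p up to 0.175, and Cd8b1, Runx3, Nkg7, Xcl1, Cd83, Pdcd1, Itgb7, Ecm1, Eno1, Il1rl1, Klrg1 and Cpxm1 were among them.

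The comparison with the animal controls asks about the same loss within the same mice, against cells that differ also in Foxp3 allele and sorting gate. Cd8a rose from 34.5 ± 16.1 to 367 ± 19.9 CPM (log2 fold change 3.53 ± 0.40, adjusted p = 0.00345) and Cd4 fell from 889 ± 87.7 to 355 ± 25.7 CPM (-1.32 ± 0.15, adjusted p = 0.00338). Foxp3 fell from 905 ± 132 to 32.2 ± 5.02 CPM (-4.81 ± 0.25, adjusted p = 5.18e-05). The genetic controls, which kept both factors, had a like level, so this fall goes with the Foxp3 allele or gate. Itgb1 (-2.63 ± 0.17, adjusted p = 8.75e-05), Nrp1 (-3.30 ± 0.27, adjusted p = 6.88e-04) and Ly6a (-4.31 ± 0.24, adjusted p = 6.45e-05) fell as well. Il2ra, the gene behind the CD25 gate of the animal controls, fell from 769.9 ± 31.0 to 473 ± 70.2 CPM with an adjusted p of 0.0497, up to 0.140 without 1 library. Cd8b1 (2.37 ± 0.53, adjusted p = 0.0880) and Runx3 (0.48 ± 0.33, adjusted p = 0.647) did not pass the test here; Runx3 averaged 70.6 ± 19.3 CPM in the animal controls.

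In the Treg signature list 1 of 39 measured members rose and 13 fell, or 2 and 20 adjusted over the list alone (list adjusted p = 1.56e-15, and adjusted p = 0.0058 with an estimated correlation), and it was called downward, as were the other lists of this paragraph. Beside Foxp3, whose fall goes with the allele or gate, the members that fell with the lowest adjusted p were Capg (-2.14 ± 0.16, adjusted p = 2.82e-04), Nrp1 and Nt5e (-1.87 ± 0.17, adjusted p = 9.25e-04), and Ecm1 rose (1 ± 0.14, adjusted p = 0.0102). For effector Treg genes, 0 of 36 measured members rose and 10 fell, or 1 and 27 adjusted over the list alone (list adjusted p = 3.04e-25, and adjusted p = 0.0058 with an estimated correlation). Lgals1 (-2.17 ± 0.25, adjusted p = 0.00338), Pdcd1 (-1.98 ± 0.27, adjusted p = 0.00845) and Icos, a co-stimulatory receptor (-1.96 ± 0.30, adjusted p = 0.0138), were among them. Some genes in both lists fell by more: Klrg1 averaged 0.0331 ± 0.0254 against 49.1 ± 19.0 CPM, Il1rl1 0.0302 ± 0.0287 against 20.9 ± 9.57 CPM, and Tigit, an inhibitory receptor, 0.268 ± 0.185 against 31.0 ± 6.30 CPM. In the homing list 1 of 29 measured members rose and 4 fell, or 2 and 12 adjusted over the list alone (list adjusted p = 3.26e-08, and adjusted p = 0.0399 with an estimated correlation): Ccr9 rose (3.39 ± 0.59, adjusted p = 0.0290), and Itgb1, Itgb7 (-0.91 ± 0.11, adjusted p = 0.00390), Gpr183 (-2.78 ± 0.31, adjusted p = 0.00333) and Cxcr6 (0.105 ± 0.0818 against 78.6 ± 20.3 CPM) fell.

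Among CD8 lineage and cytotoxic genes, 3 of 22 measured members rose and 2 fell, or 6 and 3 adjusted over the list alone, and the list was not called (adjusted p = 0.378). Cd8a, Nkg7 (1.79 ± 0.30, adjusted p = 0.0245) and Ctsw, a protease of cytotoxic cells (1.59 ± 0.26, adjusted p = 0.0188), rose, while Cst7, an inhibitor of such proteases (-1.75 ± 0.30, adjusted p = 0.0280), and the chemokine gene Ccl3, at 0.00457 ± 0 against 3.70 ± 3.54 CPM, fell. The list's median was 0.23 and its mean -0.67, while the test pointed up. It was called upward with only genes of at least 10 CPM (adjusted p = 4.29e-05) and with the genes of lowest mean left out (adjusted p = 0.00537).

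Further lists were called downward against the animal controls. T cell receptor-induced genes had 0 higher and 1 lower of 29, or 0 and 4 adjusted over the list alone (adjusted p = 0.00415), helper effector genes 0 higher and 0 lower of 18, or 0 and 6 adjusted over the list alone (adjusted p = 0.00129), and follicular helper T cell markers 0 higher and 1 lower of 12, or 0 and 4 adjusted over the list alone (adjusted p = 9.17e-05). With an estimated correlation camera gave adjusted p of 0.0433, 0.0399 and 0.0399 for these lists. Maf, a transcription factor of helper cells, did not pass on its own (-3.65 ± 0.75, adjusted p = 0.0623), nor did Cxcr5, a follicular homing receptor (-2.06 ± 0.43, adjusted p = 0.0680). IL-2 and STAT5 responsive genes had 1 higher and 6 lower of 51, or 2 and 16 adjusted over the list alone (adjusted p = 5.39e-04), a call lost in another form of the test (adjusted p = 0.0638 with an estimated correlation). CD4 lineage genes had 0 higher and 2 lower of 15, or 1 and 2 adjusted over the list alone (adjusted p = 0.0140), a call lost in the same way (adjusted p = 0.0638 with an estimated correlation) and without animal control 142114 (adjusted p = 0.0855), the members that fell being Cd4 and the deleted Zbtb7b. Without the deleted genes, Zbtb7b and Zbtb7a, that list was not called by camera (adjusted p = 0.198, mean -0.15 in place of -0.72), though fry called it downward (adjusted p = 0.0194). Co-inhibitory receptors had 0 higher and 2 lower of 15, or 1 and 3 adjusted over the list alone (adjusted p = 0.0111). Their call was lost too (adjusted p = 0.0634 with an estimated correlation), also without animal control 432614 (adjusted p = 0.0727) and with only genes of at least 10 CPM (adjusted p = 0.492).

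Markers of B cells were lower in the deficient cells than in the animal controls as a list, with 0 higher and 0 lower of 14, or 0 and 1 adjusted over the list alone (adjusted p = 0.00498). That call was lost in another form of the test (adjusted p = 0.0572 with an estimated correlation). Their summed level was 880.5 ± 179 CPM in the deficient cells, 933 ± 314 CPM in the genetic controls and 1612 ± 303 CPM in the animal controls. Gamma-delta T cell markers were called downward too, with 0 higher and 0 lower of 5, or 0 and 2 adjusted over the list alone (adjusted p = 0.00498). This call was lost as well (adjusted p = 0.0582 with an estimated correlation), at levels of 11.4 ± 3.28 against 37.1 ± 14.4 summed CPM. Fry called all 11 of the lists that camera called against the animal controls.

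Some lists were not called against the animal controls. Interferon response genes had 0 higher and 2 lower of 40, or 1 and 7 adjusted over the list alone (adjusted p = 0.115). Ly6c1 (-2.80 ± 0.34, adjusted p = 0.00500) and Ly6a were the members that fell, and the list had a median of 0.03 and a mean of -0.28. Central or resting Treg genes had 0 higher and 1 lower of 25, or 5 and 4 adjusted over the list alone (adjusted p = 0.415), and naive T cell markers had 0 higher and 1 lower of 17, or 4 and 4 adjusted over the list alone (adjusted p = 0.949). Glycolysis genes had 0 higher and 0 lower of 30, or 1 and 4 adjusted over the list alone (adjusted p = 0.128), with a mean of 0.000567 while the median and the test pointed down. The TGF-beta pathway had 0 higher and 0 lower of 19, or 1 and 1 adjusted over the list alone (adjusted p = 0.949). Oxidative phosphorylation, cholesterol synthesis, cell cycle and apoptosis genes had 0 members higher and 0 lower of 40, 25, 37 and 28 measured, and 0 and 0 adjusted over the list alone (adjusted p = 0.261, 0.639, 0.276 and 0.911). Markers of plasma cells, myeloid cells, NK cells and erythroid cells had 0 members higher and 0 lower of 5, 14, 9 and 8 measured, and 0 and 0 adjusted over the list alone (adjusted p = 0.160, 0.639, 0.911 and 0.101). The erythroid list was called upward with the mouse as a fixed term (adjusted p = 0.0335), on the 6 libraries alone (0.0480), without deficient library 142114 or 432614 (0.0105 and 0.0384) and without genetic control 8619 (0.0480). Camera with an estimated correlation gave it an adjusted p of 0.611. Most of its level in the deficient cells came from library 232614, at 81.0 summed CPM against 0.842 in 142114 and 11.9 in 432614. The interferon list was called downward without deficient library 142114 (adjusted p = 0.0196), without animal control 432614 (0.0449) and with the genes of lowest mean left out (0.0439). The test and the median pointed different ways for apoptosis (median -0.05), the TGF-beta pathway (-0.05), naive T cell markers (0.15) and interferon response genes (0.03).

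Against the animal controls 122 genes changed (limma, FDR under 0.05), 42 higher and 80 lower, and 1632 had an unadjusted p under 0.05. The groups did not overlap for 15.9% of genes, where chance gives 10%. The genes named by rule as highest were Epb4.1l5, Cpxm1, Bai2, Notch3, Zfp385a, Mcam, Cul7 and Tubb3, each under 0.1 CPM in the animal controls and between 11.5 and 51.7 CPM in the deficient cells. Among the lowest were Il9r, Fam160a1, Il1r2, Arc, Map6, Gcat and Klrg1, each under 0.1 CPM in the deficient cells and between 16 and 71.7 CPM in the animal controls. With the mouse as a fixed term, which leaves 2 residual degrees of freedom in place of 4, limma called 0 genes (1395 at an unadjusted p under 0.05, lowest adjusted p = 0.0953). All 122 genes kept an unadjusted p under 0.05 in that fit, as they did in limma on the same 6 libraries without a mouse term. They were chosen from these same libraries, so this is no separate evidence that they hold with a mouse term. With the mouse as a random effect 148 were called. The count was 74, 81 and 58 without animal controls 142114, 232614 and 432614, and between 88 and 115 without any other library. It was 52 on the 6 libraries alone, and 27 without genetic control 8619 and animal control 232614. Without the trend it was 95, 40 higher and 55 lower, of which 71 were among the 122. Of 65 called genes followed through all fits, 37 passed in every fit without 1 library. Ccr9, Nkg7, Il2ra, Ctsw, Cst7, Icos, Tigit and Ecm1 were among those that did not, with adjusted p up to 0.140.

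**Figure D2:**
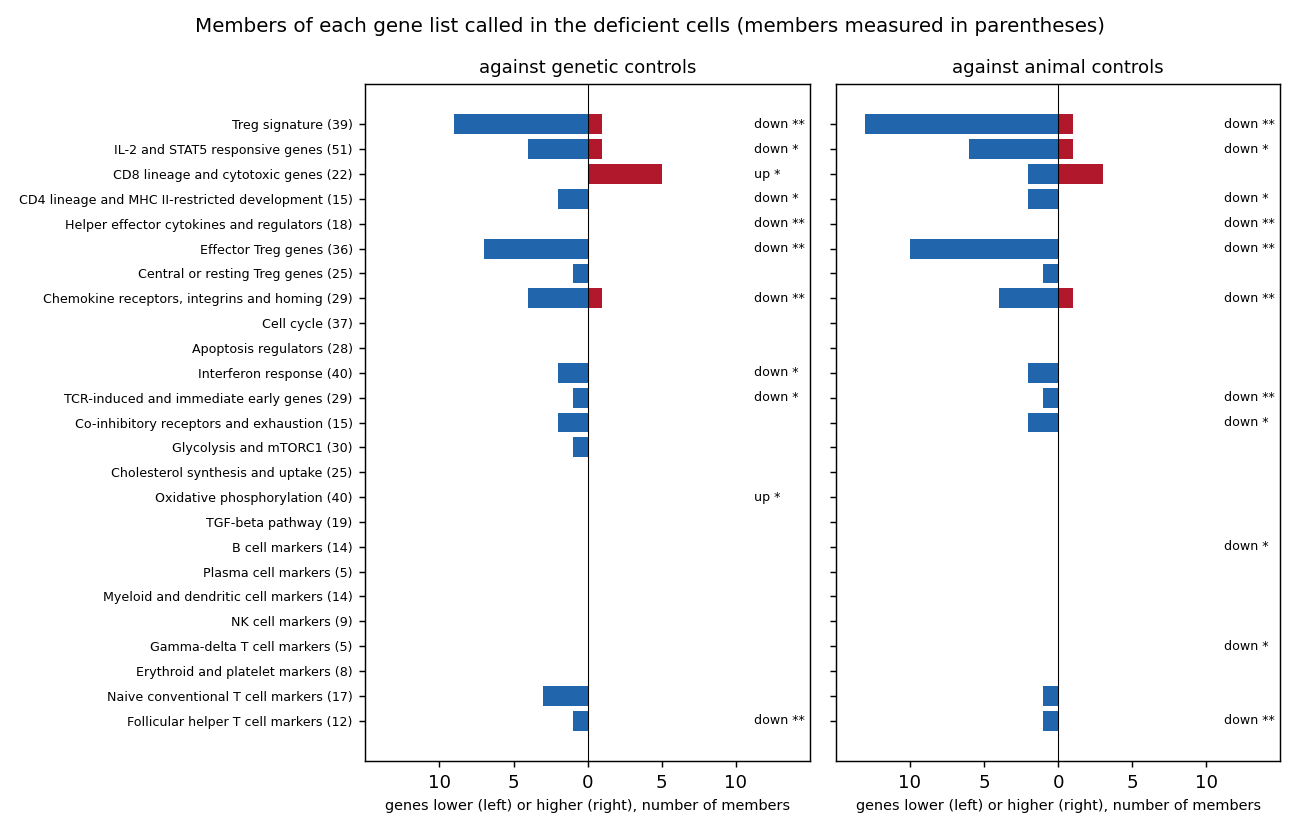
Number of members of each fixed list called lower (left) or higher (right) in the deficient cells against the genetic controls and against the animal controls. Words give the direction of a list called at an adjusted p under 0.05 with the preset correlation (1 star) and also with the estimated correlation (2 stars); effector Treg genes had 7 and 10 members lower.

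Genes changed the same way against both controls are those whose difference goes with neither the mice nor the Foxp3 allele and gate alone. There were 79 such genes, 24 higher and 55 lower, and 0 changed in opposite ways. Cd8a, Ccr9, Nkg7 and Ecm1 rose against both controls, and Cd4, Nrp1, Itgb1, Itgb7, Gpr183, Lgals1, Nt5e, Capg, Pdcd1, Ly6a and Ly6c1 fell against both. By the smaller of both folds, the genes named by rule as highest were Cpxm1, Bai2, Notch3, Epb4.1l5, Zfp385a, Mcam, Tubb3 and Bag2. Arc, Ttn, Map6, Csf1, Lgmn, Il1r2, Cxcr6 and Il1rl1 were named as lowest. Il1r2, a decoy receptor for IL-1, averaged 0.0333 ± 0.0258 CPM in the deficient cells, 18.2 ± 1.97 CPM in the genetic controls and 71.7 ± 11.9 CPM in the animal controls. A further 40 genes were called against the genetic controls alone and 43 against the animal controls alone. Independent lists of these sizes would share 0.141 higher and 0.426 lower genes, but the lists are not independent, as they share the deficient libraries. With the deficient libraries shared and neither a change nor a mouse effect simulated, the highest count in 50 draws was 0. Such draws hold no changed gene, so almost none is called and a count near 0 was fixed in advance. At an unadjusted p under 0.05 the count was 723 against a simulated mean of 158. These draws cannot tell how large an overlap the shared libraries alone would give between 119 and 122 called genes. The overlap fell to 43, 35 and 37 without genetic controls 124, 8619 and 8800. It was 52, 62 and 56 without deficient libraries 142114, 232614 and 432614, and 48, 59 and 42 without the animal controls of those numbers. Without the trend it was 59, 27 higher and 32 lower, of which 45 were among the 79. It was 14 when each comparison used its own 6 libraries, 13 without genetic control 8619 and animal control 232614, and 0 with the mouse as a fixed term.

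**Figure D3:**
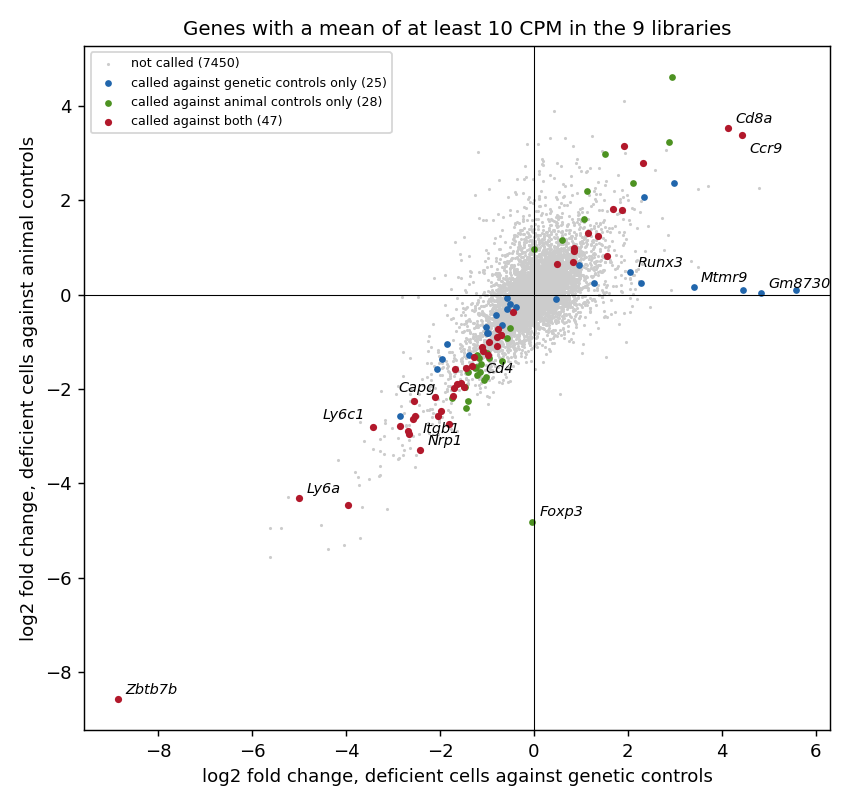
Log2 fold change of the deficient cells against the genetic controls (horizontal axis) and against the animal controls (vertical axis) for the 7550 genes with a mean of at least 10 CPM. Colours mark genes called against both controls (47), the genetic controls alone (25) or the animal controls alone (28); Foxp3 lies on the vertical axis and Mtmr9 and Gm8730 on the horizontal axis, and both axes share the deficient libraries.

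The comparison of both kinds of control asks which genes differ with the mouse line, the Foxp3 allele and the gate while both factors are present. Foxp3 was lower in the genetic controls, at 33.3 ± 7.38 CPM against 905 ± 132 CPM (log2 fold change -4.78 ± 0.25, adjusted p = 5.55e-05). Mtmr9, a phosphatase-family protein, was lower too, at 25.7 ± 5.79 against 251 ± 97.9 CPM (-3.24 ± 0.30, adjusted p = 0.00367), as was its neighbour Xkr6 at 0.0114 ± 0.00648 against 23.0 ± 3.47 CPM (adjusted p = 0.00388, and 0.0739 without animal control 432614). The pseudogenes Gm8730 (16.8 ± 2.44 against 489 ± 156 CPM, -4.81 ± 0.35, adjusted p = 6.16e-04) and Gm9625 (3.80 ± 0.987 against 176 ± 62.7 CPM, -5.49 ± 0.43, adjusted p = 9.37e-04) fell as well; they fall outside the naming rule and were chosen after their values were seen. Zbtb7b (0.28 ± 0.52), Zbtb7a (-0.32 ± 0.25), Cd4 (-0.06 ± 0.15), Cd8a (-0.61 ± 0.40), Cd8b1 (-0.61 ± 0.53), Runx3 (-1.57 ± 0.33) and Il2ra (-0.20 ± 0.14) did not pass the test, the lowest adjusted p being 0.232 for Runx3. These 5 genes, 0 higher and 5 lower, were all that passed in limma with the trend, with 907 at an unadjusted p under 0.05 and 10.4% of genes not overlapping, where chance gives 10%. The count was between 4 and 10 without 1 library (10 without genetic control 124), 3 on the 6 libraries alone and 1 without genetic control 8619 and animal control 232614. Without the trend it was 32, 9 higher and 23 lower, and with values under 1 CPM raised to 1 CPM it was 11, 2 higher and 9 lower. Of the 5 genes, 5 were among the 32 and 4 among the 11.

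Between the controls 9 lists were called, and camera with an estimated correlation called 0 of them (lowest adjusted p = 0.0706). Fry called 2 of them, Treg signature genes and B cell markers, both downward (adjusted p = 0.0225 each). Treg signature genes were lower in the genetic controls, with 0 higher and 1 lower of 39, or 0 and 1 adjusted over the list alone (adjusted p = 1.42e-04), Foxp3 being the called member. B cell markers were lower too, with 0 higher and 0 lower of 14, or 0 and 2 adjusted over the list alone (adjusted p = 2.81e-04). Both had an adjusted p = 0.0706 with an estimated correlation. Effector Treg genes had 0 higher and 0 lower of 36, or 0 and 0 adjusted over the list alone (adjusted p = 0.00672), CD8 lineage genes 0 higher and 0 lower of 22, or 0 and 3 adjusted over the list alone (adjusted p = 0.00954), and plasma cell markers 0 higher and 0 lower of 5, or 0 and 1 adjusted over the list alone (adjusted p = 0.00920). These 3 lists were lower as well, and each had an adjusted p = 0.271 with an estimated correlation. Central Treg genes were higher, with 0 higher and 0 lower of 25, or 2 and 0 adjusted over the list alone (adjusted p = 0.00319), and an adjusted p = 0.147 with an estimated correlation. Cell cycle genes, with 0 higher and 0 lower of 37, or 0 and 0 adjusted over the list alone (adjusted p = 0.00672), and interferon response genes, with 0 higher and 0 lower of 40, or 1 and 0 adjusted over the list alone (adjusted p = 0.00728), were higher. Both had an adjusted p = 0.271 with an estimated correlation. Erythroid markers were higher, with 0 higher and 0 lower of 8, or 0 and 0 adjusted over the list alone (adjusted p = 0.0249), and an adjusted p = 0.536 with an estimated correlation. Cd79b, a chain of the B cell receptor (-1.74 ± 0.38, adjusted p = 0.238), and Tnfrsf9, a co-stimulatory receptor (-0.65 ± 0.20, adjusted p = 0.544), did not pass.

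Of these 9 calls between the controls, those of 7 lists were lost when single libraries were left out. Without genetic control 8619 those of cell cycle (adjusted p = 0.285) and erythroid genes (0.717) were lost, and without 232614, an animal control, that of plasma cell markers (0.122). Without genetic control 124 those of CD8 lineage (0.211) and interferon genes (0.159) were lost. Without genetic control 8800 those of CD8 lineage, effector Treg and plasma cell genes were lost (adjusted p = 0.0663 each). Without animal control 142114 those of CD8 lineage (0.114) and erythroid genes (0.0657) were lost. Without animal control 432614 those of central Treg (0.0715), effector Treg (0.104), interferon (0.0944) and erythroid genes (0.142) were lost. Of the lists not called, IL-2 responsive genes, CD4 lineage genes, helper effector genes and homing genes had 0 members higher and 0 lower of 51, 15, 18 and 29 measured, and 0 and 0 adjusted over the list alone (adjusted p = 0.0511, 0.510, 0.908 and 0.558). T cell receptor-induced genes, co-inhibitory receptors, apoptosis genes, glycolysis, cholesterol synthesis and oxidative phosphorylation had 0 members higher and 0 lower of 29, 15, 28, 30, 25 and 40 measured, and 0 and 0 adjusted over the list alone (adjusted p = 0.50, 0.199, 0.882, 0.199, 0.0647 and 0.485). Markers of myeloid cells, NK cells, gamma-delta T cells and follicular helper T cells had 0 members higher and 0 lower of 14, 9, 5 and 12 measured, and 0 and 0 adjusted over the list alone (adjusted p = 0.477, 0.934, 0.148 and 0.619). IL-2 responsive genes were called downward without any 1 of the deficient libraries 142114, 232614 and 432614 (adjusted p = 0.0211, 0.0375 and 0.0243), without genetic control 124 (0.0214) and without animal control 232614 (0.0145). The same call came on the 6 libraries alone (adjusted p = 0.00948), with a floor of 1 CPM (0.0378), with the genes of lowest mean left out (0.0344) and with only genes of at least 10 CPM (0.0163). Cholesterol synthesis was called upward without genetic control 124 (adjusted p = 0.0271), and gamma-delta T cell markers downward without deficient library 142114 (adjusted p = 0.0378), on the 6 libraries alone (0.0252) and with that floor (0.0378). The TGF-beta pathway had 0 higher and 0 lower of 19, or 2 and 1 adjusted over the list alone (adjusted p = 0.634), and naive T cell markers had 0 higher and 0 lower of 17, or 1 and 0 adjusted over the list alone (adjusted p = 0.510). The test pointed down for T cell receptor-induced genes (median 0.06, mean 0.21) and up for NK cell markers (median -1.09, mean -0.18), apoptosis (mean -0.05) and naive T cell markers (mean -0.01).

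With the estimated correlation, the calls of Treg signature, effector Treg, homing, helper effector and follicular helper genes held against both controls, and that of T cell receptor-induced genes against the animal controls. These were 5 of the 11 lists called against the genetic controls and 6 of the 11 against the animal controls. Not every lost call goes with correlated members. The estimates for B cell, gamma-delta T cell, CD4 lineage and co-inhibitory lists were -0.0342, -0.0848, -0.0312 and -0.0392, all under the preset 0.01. Why the calls of those lists were lost in that form of the test was not tested.

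**Figure D4:**
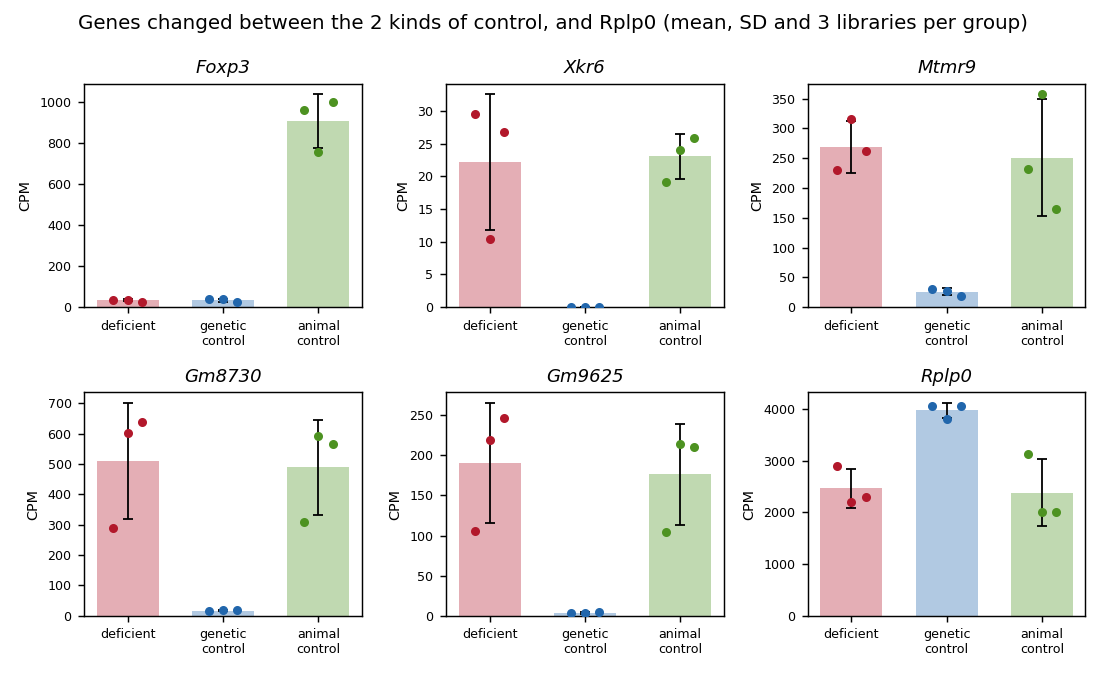
Level in CPM (linear axis from 0) of the 5 genes called between the controls, and of Rplp0, in the deficient cells, genetic controls and animal controls. Bars are means, error bars are SD, and points are the 3 libraries of each group; Rplp0 averaged 3969 CPM in the genetic controls against 2463 and 2382 CPM in the others.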

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

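All tests of Foxp3, of Rplp0 and of ribosomal protein genes in this part were chosen only after the result was seen, including what each would have to show. All 5 results below stand out because the effect in the deficient cells differed with the kind of control used, by the limma contrast between both controls.

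Foxp3 measured 32.2 ± 5.02 CPM in the deficient cells, 33.3 ± 7.38 CPM in the genetic controls and 905 ± 132 CPM in the animal controls, a log2 difference between the controls of -4.78 ± 0.25 (SE, n = 3 against 3, adjusted p = 5.55e-05). Cells without Foxp3 in the YFP gate would lower the other Treg genes by about as much, and the 29 other Treg signature genes with a mean of at least 10 CPM had a median difference of -0.31 with an SD of 0.67 between genes, which argues against such cells as the whole source. The modified Foxp3 allele or the YFP gate itself may be the source, since Foxp3 differed by -0.0339 (SE 0.25) between the groups that share both. Allele and gate cannot be told apart for Foxp3, because the design changes both together.

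Gm8730 (chromosome 8, 102864845 to 102865798) and Gm9625 (chromosome 13, 67810246 to 67811200) were lower in the genetic controls than in the animal controls, with log2 differences of -4.81 and -5.49, and both are annotated as processed pseudogenes with 98.7% and 97.4% identity to Rplp0, a ribosomal protein gene. Lower ribosomal protein transcripts in the genetic controls are argued against by 78 other genes of that class, whose median difference was -0.0886 with an SD of 0.23. Reads of Rplp0 placed at its copies in cells of the deficient line, as a sequence variant in that line would bring about, may be the source: Rplp0 was higher in every genetic control (3803 to 4052 CPM) than in every animal control (2012 to 3120.4 CPM) and deficient library (2198 to 2899.6 CPM), a log2 difference from the animal controls of 0.77 ± 0.16 that did not pass on its own (adjusted p = 0.232). The sum of Rplp0, both copies and Rplp0-ps1 was still higher in the genetic controls, at 3990.1 ± 143 CPM against 3058 ± 417 CPM in the animal controls (SD, n = 3), so reads moved between these genes would account for part of the Rplp0 difference only. The labels give the same mixed strain background for all libraries, no variant can be read from values per gene, and a difference in transcription of the copies was not tested.

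Mtmr9 (chromosome 14, 63519651 to 63543982) measured 269 ± 44.0 CPM in the deficient cells, 25.7 ± 5.79 CPM in the genetic controls and 251 ± 97.9 CPM in the animal controls, a log2 difference between the controls of -3.24 ± 0.30. Xkr6 (chromosome 14, 63606503 to 63820809), which starts 62.5 kb after it, measured 22.2 ± 10.4, 0.0114 ± 0.00648 and 23.0 ± 3.47 CPM, a difference of -11.11 ± 1.08 that rests on values near the lowest in the table. Mtmr9 and Xkr6 were at like levels in the deficient cells and the animal controls of the same mice. Their difference from the genetic controls thus goes with the mice and not with the loss of both factors.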

How the results depend on the processing

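In this part, 6 alternatives were chosen only after the result was seen: a floor of 1 CPM, robust moderation, trimmed-mean rescaling, genes with a mean of at least 10 CPM alone, genetic control 8619 and animal control 232614 both left out, and the deleted genes left out of the gene lists. Counts below are given for deficient cells against genetic controls, against animal controls, between the controls, and the same way against both, whose reported values are 119, 122, 5 and 79. Leaving out 1 library gave 48 to 93, 58 to 115, 4 to 10, and 35 to 62. Every gene called with all libraries kept its sign in each of these fits. That was fixed in advance, because the compared groups do not overlap for any called gene. The 6 compared libraries alone gave 22, 52, 3 and 14, all of them called with 9 libraries except 4 of the 52; an FDR under 0.01 gave 34, 43 and 26 for the first, second and last. In the paired fit, with the mouse as a fixed term, limma called 0 against the animal controls (1395 at an unadjusted p under 0.05) and 0 the same way, and Zbtb7b then had -8.58 with an adjusted p of 0.170, the highest of its alternatives (lowest 1.74e-05). Its fold depends on values under 1 CPM and was -6.54 with a floor of 1 CPM (adjusted p = 3.29e-04). The lists of the paired fit were 12 and those with the mouse as a random term 11; both include all 11 reported ones, erythroid markers were added in the fixed form, and 148 genes were called with the random term. Fewer libraries and residual degrees of freedom lower such counts. Genetic control 8619 and animal control 232614 both left out gave 21, 27, 1 and 13. Limma without trend gave 32 between the controls and a floor of 1 CPM gave 11; the cause was not tested. The lists called, reported as 11, 11 and 9, were 7 to 11, 10 to 13 and 5 to 11 without 1 library. They were 5, 6 and 0 with an estimated correlation, and 9, 10 and 9 without the deleted genes in the lists. Between the controls they were 2 with fry, 5 with both libraries left out and 5 with genes of at least 10 CPM alone. In the last of these, B cell, plasma cell and erythroid markers had 2, 0 and 0 members left, too few to be tested. The cause of the other differences was not tested.

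Zbtb7a, 0.01 against the genetic controls, ran from -0.17 to 0.17 without 1 library (-0.17 without genetic control 124, -0.10 without deficient library 432614) and was -0.00699 with trimmed-mean rescaling (adjusted p from 0.893 to 1 over all alternatives). Foxp3, -0.03 in that comparison, ran from -0.23 to 0.10 (0.08 without genetic control 124, 0.0537 without 8619, 0.10 without deficient library 432614) and was 0.0537 with both libraries left out. Cd4 between the controls, -0.06, ran from -0.19 to 0.11 (0.11 without genetic control 8619, 0.02 without animal control 432614) and was 0.0887 with both left out. None of these 3 was called under any alternative. All other genes followed kept their direction in every alternative. Quantile normalization repeated, the mouse as a random term where it applies, and trimmed-mean rescaling kept the calls of all 67, 65 and 5 called genes followed through the fits. These alternatives could change little, so the kept calls are weak evidence. The values were already quantile-normalized, so repeating that step was nearly fixed in advance. Trimmed-mean rescaling moved the libraries by only -0.0274 to -0.0598 log2, and the consensus correlation of the random term was 0.0493. Limma without trend kept 42, 45 and 5, the 6 libraries alone 17, 37 and 3, and both libraries left out 18, 24 and 1. The alternatives set for counts (RLE or library-size scaling, DESeq2, voom and count filters) and for pseudocounts were not run, because the table holds log2 values. The unknown read depth limits the low genes: 47 of the 119 and 46 of the 122 called genes had a group mean log2 value under 0. Their folds rest on values near the lowest in the table. With a floor of 1 CPM, 51 of 67 and 58 of 65 called genes followed kept their calls, and 16 and 7 lost them. Those counts cover low and other genes together.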

Other observations

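The single genes given outside the lists and the tests on Cd8a and Cd4 were chosen only after the result was seen, and so was what the splits of the samples would have to show, while the list of immature T cell genes was chosen before its own result was seen. Beyond the lists, the deficient cells were higher in Cd81, a tetraspanin of lymphocyte membranes (636 ± 44.3 CPM against 218 ± 18.5 CPM in the genetic and 359 ± 30.8 CPM in the animal controls, SD, n = 3), and lower in Cd82, another tetraspanin (241 ± 14.9 against 606 ± 61.4 and 694 ± 144 CPM), with adjusted p of 5.01e-04 and 0.0130 for Cd81 and 0.00438 and 0.00200 for Cd82. The surface antigen gene Ly6e fell along with its relatives Ly6a and Ly6c1, to 1709 ± 258 from 2926 ± 106 and 3595 ± 49.6 CPM (adjusted p = 0.00550 and 9.25e-04). Samhd1, which breaks down deoxynucleotides, fell to 301 ± 15.5 from 644 ± 34.6 and 647 ± 24.6 CPM (0.00111 and 9.25e-04). Ass1, an enzyme of arginine synthesis, fell to 16 ± 5.92 from 96.7 ± 14.7 and 117 ± 4.57 CPM (0.00630 and 0.00338). Slc25a4, which exchanges ATP and ADP across the mitochondrial membrane, rose to 597 ± 55.1 from 233 ± 46.1 and 253 ± 28.2 CPM (0.00550 and 0.00867). Igsf23 (231 ± 37.3 against 46.7 ± 9.59 and 33.5 ± 4.39 CPM) and Trpm1, an ion channel gene (128 ± 17.6 against 33.8 ± 3.30 and 14.4 ± 1.38 CPM), rose too. Smpdl3a, a phosphodiesterase gene, fell to 114 ± 25.3 from 355 ± 52.1 and 420.2 ± 71.5 CPM. For Cd82, Ly6e, Samhd1, Ass1, Slc25a4, Igsf23 and Smpdl3a the calls held in every fit without 1 library; Cd81 missed the threshold against the animal controls (adjusted p up to 0.0631) and Trpm1 against the genetic controls (up to 0.0785) in some of them, and every call against the animal controls ended with the mouse as a fixed term.

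Further single genes changed. S100a4, also chosen after its values were seen, is a member of the effector Treg list tested above. For the other genes of this paragraph, no class they belong to was tested. Actg1, cytoplasmic actin, fell to 1266 ± 24.2 from 1737 ± 31.7 and 1641 ± 38.8 CPM (adjusted p = 0.00586 and 0.0135), and Ahnak, a large scaffold protein, fell to 41.8 ± 14.9 from 157 ± 22.8 and 221 ± 43.5 CPM (0.0206 and 0.00500). Tubb5, a beta-tubulin, rose to 776 ± 44.2 from 437 ± 85.8 and 409 ± 42.3 CPM (0.0307 and 0.0161), as did Hmgn2, a nucleosome-binding protein, to 257 ± 16.8 from 81.8 ± 20.7 and 74.2 ± 19.3 CPM (0.0229 and 0.0109). S100a4, a calcium-binding protein of motile cells, fell to 1.34 ± 0.15 from 15.9 ± 5.52 and 21.3 ± 2.97 CPM (0.0296 and 0.0136). Of the 9 fits without 1 library, the calls against the genetic and the animal controls passed in 9 and 5 for Actg1, 6 and 9 for Ahnak, 3 and 5 for Tubb5, and 4 and 9 for Hmgn2. For S100a4 they passed in 0 and 6 (limma), with adjusted p up to 0.138, so its call against the genetic controls needs every library.

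Cd8a was higher and Cd4 lower in the deficient cells, and CD8 T cells among the sorted cells could bring both, although deficient cells and genetic controls were sorted on YFP made from the Foxp3 allele, a gate that selects against ordinary CD8 T cells. For the fall of Cd4 the tables argue against this: such cells would dilute Foxp3 as much, yet Foxp3 differed from the genetic controls by -0.0339 and Cd4 by -1.27 ± 0.15, a gap of 1.23 with an SE of 0.29, unless Foxp3 rose in the remaining cells by the same amount. For the rise of Cd8a the source cannot be told apart from expression in the Treg cells themselves: Cd8b1 rose as well, by 2.98 ± 0.53, and bulk values do not show which cells carry the transcripts. The biological explanation that the design names, the loss of Thpok and LRF, stays open and was not tested apart from these.

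A hypothesis that the deficient cells hold more transcripts of immature T cells came from Sox4, which rose against the animal controls alone (2.97 ± 0.52, adjusted p = 0.0290, up to 0.106 without 1 library) and did not pass against the genetic controls (1.5 ± 0.52, adjusted p = 0.302). Sox4 was left out of the test, which was made with a list of 12 thymocyte genes, of which 8 were measured and 2 had a mean of at least 10 CPM. Camera gave an adjusted p of 0.948 against both controls, with median log2 differences of 0.46 and -0.39, so no value decides it. Of its members, limma called 0 in both comparisons, with 1 and 2 at an unadjusted p under 0.05. Themis, a signalling protein of developing T cells, measured 93.4 CPM in the deficient cells, 47.9 CPM in the genetic and 30.6 CPM in the animal controls, with adjusted p of 0.540 and 0.170.

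Other splits of the libraries were counted to see whether chance can be excluded. For the 79 genes changed the same way against both controls, 1 of 100 splits of the 9 libraries, the real one, gave as many. The other splits drawn thus gave fewer genes, but this does not exclude chance, because libraries of the same mouse are not exchangeable. Of the 49 splits that part all 3 mice of the deficient cells and animal controls, as the real one does, 1 gave as many, and the 42 that part 2 mice and the 9 that part 1 gave 0 in limma. This concerns fits without a mouse term, and with the mouse as a fixed term the overlap was 0. The highest of the others, 67, came from the only other split drawn that kept the deficient libraries together as the group compared and mixed both kinds of control. As a single split of that kind was drawn and it shares the deficient libraries with the real one, it says little about the choice of control. The 3 splits with the deficient libraries as a control gave 0 in limma, and the 95 splits that parted the deficient libraries gave at most 1 gene. Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. The real splits gave 22, 52 and 3 genes for the deficient cells against genetic controls, against animal controls, and between the controls, and the highest other split gave 0 in each. For lists the real splits gave 10, 12 and 11 and the highest others 6, 4 and 5. In each of these, 1 of 10 splits, the real one, gave as many. Against the animal controls, the other splits that part all 3 mice, as the real one does, gave at most 0 genes and 3 lists, and those that part 1 mouse at most 0 genes and 4 lists.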
